A study of Mus musculus with 8 samples.

How the data were processed

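The series holds bulk RNA-seq of sorted skeletal cells from mice at postnatal day 10, with 4 libraries from spine and 4 from long bones. Group, replicate number and sex were taken from the labels, with 2 males and 2 females per group. The labels name the samples biological replicates and do not say how many animals went into each, so p-values measure the spread between these samples. Per the labels' protocols, RNA was extracted with a column kit and libraries were made with SMART-Seq v4 and Nextera XT chemistry, which does not mark the strand. Per the submitters' processing notes, bcl2fastq 2.19, STAR 2.5.2 and Cufflinks 2.1.1 were used with genome build GRCm38, and further settings are not given in the sources used here. The deposited values are FPKM per protein-coding gene, as the authors made them. FPKM divides by transcript length and by the library's total, so a gain in a few abundant genes lowers all others, and sums differ between libraries.

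The table had 22053 rows with 22007 gene identifiers, and the 46 further rows that share an identifier were kept as separate features. The 40 rows with a low-data status were kept. No pair of libraries held identical values. Of the identifiers, 98.9% matched GENCODE M21, and in 82.1% of these the listed start lay 1 below the annotated one, so 1 was added to each start. Read totals were not used here. A search for the steps that single fragments leave in genes with low values gave relative depth for a few pairs of libraries. It was 1.75 for vSSC replicate 4 against vSSC replicate 1, resting on 10 genes, the fewest accepted. For lbSSC replicate 4 against lbSSC replicate 1 it was 1.09, resting on 51 genes. Absolute depth stayed unknown. No interval from counts is therefore given, and the precision of each value rests on the replicates.

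Values were transformed to log2(FPKM + 1) in R 4.3.3, and the 10729 genes with an FPKM of at least 1 in at least 4 of the 8 libraries were tested with limma 3.58.1 (linear model, empirical Bayes with a variance trend). The site comparison was vSSC minus lbSSC over all 8 libraries with no covariate, the sex comparison male minus female with site as a covariate, and the interaction was that of site and sex. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Gene lists with at least 3 tested members were tested with camera on the same fit with a preset gene correlation of 0.01, adjusted over 32 lists, and beside it with an estimated correlation and with the rotation test fry. Of these lists 21 passed, 10 higher and 11 lower in vSSC, 1 passed with an estimated correlation and 22 passed with fry. Counts of called members are given adjusted over all genes and adjusted over the list alone. Library similarity was the mean Spearman distance between groups minus that within groups, tested exactly over 35 splits.

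The design, 37 gene lists and the naming rule were set before the data were examined. The rule takes the 12 largest increases and 12 largest decreases among called genes whose groups do not overlap, leaving out gene models without a proper symbol. It also takes up to 4 members with the smallest p in each list, all genes of the sorting markers, and Zic1, Pax1 and Mfge8 by name. For the sexes it takes the Y-linked and X-escape lists and up to 5 further called genes. Many of the genes so chosen are summarised by counts, and 1 list and some genes of it are not reported here. Some listed symbols were not analysed here, as they matched no row used.

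Alternatives were pseudocounts of 0.1 and 0.01, no filter, a filter at an FPKM of 5, median-of-ratios scaling, quantile normalization, rescaling to one sum, no variance trend, library weights, sex as a covariate, the replicate number as a block, and each library left out in turn with the tested genes kept. Added after the data were seen were fits without both vSSC replicates 1 and 3, with the trend on transcript length removed by loess with a span of 0.5, with the ribosomal protein share as a covariate, and with the filter reapplied after a library was left out. The last was the first form run. It drops genes expressed at a single site or sex from the test, so the tested genes were then held fixed and both forms are given. The procedure was tested on simulated data with the site design and 10729 genes. The noise was drawn independently for each gene and few genes were changed, whereas real genes share variation and many were called. The procedure recovered 24.0% of genes changed by 0.5 on the log2 scale, 83.6% at 1, 100% at 2 and 99.2% at 3, with 5.3% wrong calls. These rates hold for that setting and do not give the error of the real calls.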

Results

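RNA was sequenced from 8 libraries of wild-type mice at postnatal day 10. In 4 libraries the cells came from the spine (candidate vertebral skeletal stem cells, vSSC) and in 4 from the long bones (long bone skeletal stem cells, lbSSC), with 2 male and 2 female libraries per group. Both groups were sorted on the same surface phenotype, negative for CD31, TER119, CD45, Thy, 6C3 and CD105 and positive for CD200. Expression was given in FPKM, fragments scaled to transcript length and to the mapped fragments of the library. The FPKM of a library summed to between 460302 and 571869 over the protein-coding genes listed, with means of 548787 ± 26008 in vSSC and 495271 ± 29943 in lbSSC. Read totals per library were not used here, so the counting error behind a single value is unknown. Between 10337 and 10753 genes per library had an FPKM of at least 1. Values below are mean FPKM ± SD with n = 4 per group, and differences are vSSC minus lbSSC on the log2(FPKM + 1) scale ± SE, which understates the change of genes with low FPKM. Adjusted p-values are from limma for genes and from camera for gene lists, with Benjamini-Hochberg adjustment.

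The first question was whether the cells of the 2 skeletal sites differed as a whole. Libraries of one site resembled each other more than libraries of the other site. Spearman's rho over 10729 genes lay between 0.960 and 0.982 within the groups and between 0.906 and 0.955 across them. The mean distance between groups exceeded that within groups by 0.0349, the largest of all 35 ways to split the libraries into 4 and 4 (exact permutation test, one-sided, p = 0.0286, the smallest p this design allows). The first principal component, with 56.4% of the variance, held the vSSC libraries on one side and the lbSSC libraries on the other.

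**Figure D1:**
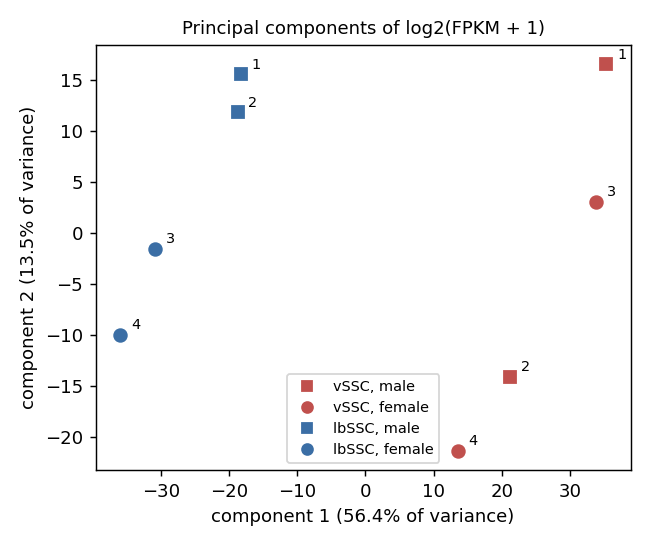
Principal components of log2(FPKM + 1) for the 8 libraries, with component 1 on the x axis (56.4% of the variance) and component 2 on the y axis (13.5%). Each point is a library with its replicate number, coloured by site and shaped by sex, and the sites lie apart along component 1.

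Genes that mark body position were among the largest differences between vertebral and long bone cells. Zic1, a zinc finger transcription factor of the dorsal somite and neural tube, reached 39.2 ± 5.05 FPKM in vSSC and 0.116 ± 0.126 in lbSSC, a difference of 5.17 ± 0.14 (adjusted p = 1.57e-09). Pax1, a transcription factor of the sclerotome from which vertebrae form, was at 39.4 ± 7.02 against 2.27 ± 0.838 FPKM (3.65 ± 0.20, adjusted p = 5.80e-07). In the opposite direction, Shox2, a transcription factor of proximal limb growth, was at 0.388 ± 0.110 in vSSC and 40.7 ± 4.86 FPKM in lbSSC (-4.90 ± 0.13, adjusted p = 1.57e-09). Pitx1, which specifies hindlimb identity, was at 0.258 ± 0.0754 against 28.8 ± 6.88 FPKM (-4.54 ± 0.17, adjusted p = 1.69e-08). In all 4 genes every library of one site lay above every library of the other.

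Of 10729 genes tested, 2518 (23.5%) differed between the sites, 1534 higher and 984 lower in vSSC. By at least 1 on the log2 scale, 210 were higher and 295 lower. The groups did not overlap in 2769 genes, 25.8% of those tested, where chance gives 2.86%. The split of calls depended on scaling. The median difference of all genes was 0.08 as deposited, -0.003 after median-of-ratios scaling, 0.03 after quantile normalization and -0.05 after rescaling each library to one sum, and the share of calls higher in vSSC was 60.9%, 49.5%, 50% and 42.5%. The count also depended on single libraries: it was 1673 without vSSC replicate 1, 1646 without vSSC replicate 3, 1534 without lbSSC replicate 3 and 1589 without lbSSC replicate 4. In fits chosen after the data were seen, it was 1095 without both vSSC replicates 1 and 3 and 623 with the ribosomal protein share of each library as a covariate.

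Besides Zic1 and Pax1, genes with large increases in vSSC were Hoxb7 (3.65 ± 0.15), Slc6a12, a betaine and GABA transporter (3.01 ± 0.23), Hoxb9 (2.98 ± 0.15), Zic4 (2.88 ± 0.14), Nnat (2.87 ± 0.33) and Hoxb6 (2.72 ± 0.15). Chrdl1, a secreted antagonist of bone morphogenetic proteins, followed with 68.3 ± 8.02 against 10.2 ± 1.18 FPKM (2.63 ± 0.13). Eln, which encodes elastin, was at 215.5 ± 108.3 against 33.7 ± 5.15 FPKM (2.54 ± 0.25), and S100a8, a calcium-binding protein of neutrophils, at 155.2 ± 37.7 against 30.9 ± 19.7 FPKM (2.53 ± 0.42). The difference of S100a8 was 1.35 with an adjusted p of 0.210 with the ribosomal protein share as a covariate. Zic1 and Zic4 overlap in the genome, and Nnat lies within Blcap, and how reads of such pairs were shared out is not given in the sources used here.

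The largest decrease was that of Msmp, a small secreted protein of the microseminoprotein family, from 757.1 ± 404.9 FPKM in lbSSC to 7.50 ± 6.79 in vSSC (-6.61 ± 0.46, adjusted p = 2.64e-06). Besides Shox2 and Pitx1, the list went on with Mab21l2 (-4.15 ± 0.14), the T-box factor Tbx15 (-3.93 ± 0.28), Rpl39l (-3.78 ± 0.23), Matn1, a cartilage matrix protein (-3.61 ± 0.20), and the secreted Wnt antagonist Sfrp1 (-3.35 ± 0.15). Otor (-3.25 ± 0.21), Bpifb1 (-3.12 ± 0.18) and Plxdc2 (-2.80 ± 0.13) were also among the 12. Cryba2, a crystallin, was listed at 0 in all 4 vSSC libraries and at 9.88 ± 7.33 FPKM in lbSSC. Mab21l2 overlaps Lrba, Msmp overlaps Rgp1, Shox2 overlaps Rsrc1 and Rpl39l resembles Rpl39, so their levels carry the uncertainty of shared reads. On GRCm38, Zic1 lies on chromosome 9 at 91358058 to 91365810, Pax1 on chromosome 2 at 147361925 to 147393295, Shox2 on chromosome 3 at 66971727 to 66981771 and Msmp on chromosome 4 at 43583216 to 43584494.

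**Figure D2:**
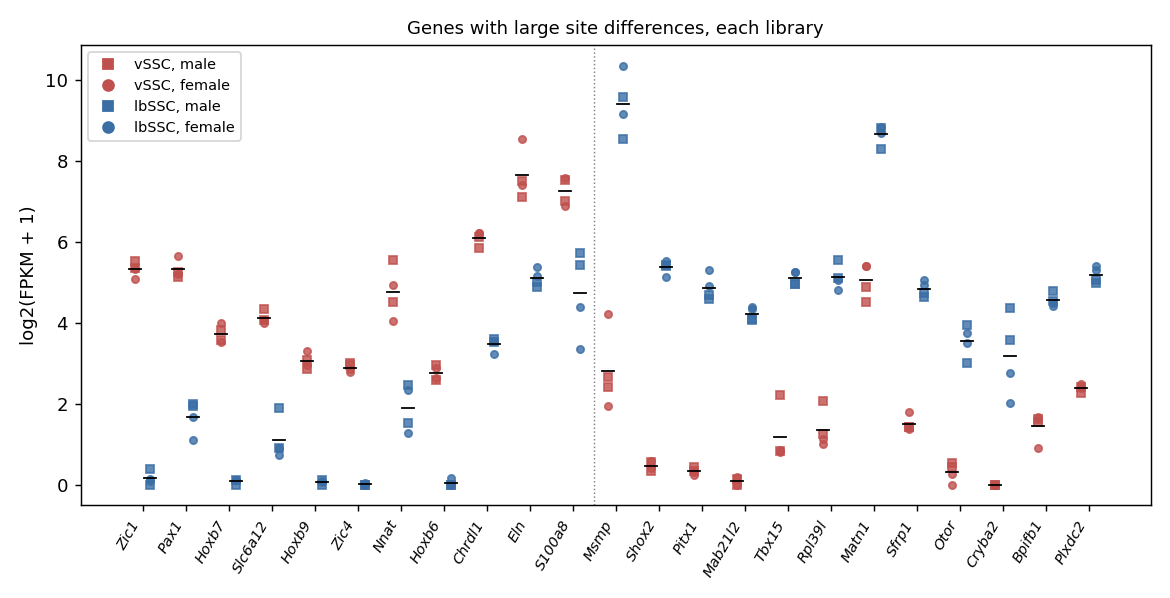
Expression as log2(FPKM + 1) on the y axis of 11 genes with large increases (left of the dotted line) and the 12 with the largest decreases in vSSC (right), along the x axis. Each point is a library, lines are group means of n = 4, and in each gene the points of the sites do not overlap.

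Axial patterning genes rose as a group. Of 8 tested members of the sclerotome and axial transcription factor list, 6 were higher and 1 lower in vSSC, with the same counts adjusted over the list alone (median 1.37, adjusted p = 0.000242). Its call was lost with adjusted p = 0.0554 with an estimated correlation. The study is known for Zic1 and Pax1, so this list is not independent evidence. The member that was lower was Tbx18, a factor of the somite's anterior part, at 1.04 ± 0.161 against 4.70 ± 0.711 FPKM (-1.47 ± 0.15, adjusted p = 5.54e-05). Limb transcription factors fell, with 8 of 15 lower and 4 higher, also adjusted over the list alone (median -0.59, adjusted p = 0.000277; adjusted p = 0.0554 with an estimated correlation). Tbx5 and Tbx4, factors of forelimb and hindlimb outgrowth, differed by -2.03 ± 0.16 and -1.98 ± 0.18. With 1 library left out and the filter on low values reapplied, a setting chosen after the data were seen that leaves genes of one site untested, the axial list had adjusted p from 0.182 to 0.339 without a vSSC library and the limb list from 0.291 to 0.436 without an lbSSC library.

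Hox genes encode position along the body axis, and the lists of groups 1 to 4 and 5 to 9 rose in vSSC. Of 14 tested genes of groups 5 to 9, 12 rose in vSSC and none fell, and 13 rose adjusted over the list alone (median 1.26, adjusted p = 4.22e-10). This was the one list whose call held with an estimated correlation (adjusted p = 0.0209). Hoxb5, Hoxb6, Hoxb7, Hoxb8 and Hoxb9 lay under 1 FPKM in lbSSC. They were therefore tested through vSSC alone and could only lie higher. The list's call also held without a vSSC library and with the filter reapplied, which leaves these genes untested. Hoxb7 was at 12.3 ± 2.07 FPKM in vSSC and 0.0582 ± 0.0389 in lbSSC (adjusted p = 5.45e-08), and Hoxb8 was at 3.60 ± 1.09 FPKM in vSSC and listed at 0 in all lbSSC libraries. In groups 1 to 4, 5 of 6 rose, and 5 rose and 1 fell adjusted over the list alone (median 1.04, adjusted p = 0.00153; adjusted p = 0.0554 with an estimated correlation). Without a vSSC library and with the filter reapplied its adjusted p ran from 0.114 to 0.208. In this list Hoxa2, Hoxb3 and Hoxd4 were likewise tested through vSSC alone. Hoxb2 was at 24.2 ± 2.94 against 3.60 ± 0.759 FPKM (2.46 ± 0.15). Groups 10 to 13 did not pass as a list (adjusted p = 0.0530), and passed as lower among genes with an FPKM of at least 5 (0.00130), with fry (0.0210), with a pseudocount of 0.1 (0.0478), without lbSSC replicate 2 (0.0344), without lbSSC replicate 4 (0.0417) or without vSSC replicate 4 (0.0448). It also passed in fits chosen after the data were seen, such as that with the length trend removed (0.0306). Of its 6 members 3 were lower, Hoxa11 (-1.43 ± 0.13), Hoxa10 (-0.99 ± 0.13) and Hoxa13 (-1.19 ± 0.29), and 1 higher, Hoxd10 (1.93 ± 0.19), also adjusted over the list alone. The filter at an FPKM of 5 leaves the called members Hoxd10 and Hoxa13 untested, so that pass rests on a list without its only higher member.

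Type I collagen was much lower in vertebral cells while cartilage matrix genes split. Col1a1 was at 723.4 ± 71.5 FPKM in vSSC and 4093 ± 836 in lbSSC (-2.48 ± 0.15, adjusted p = 1.00e-06), and Col1a2 differed by -1.74 ± 0.14. Omd, a keratan sulfate proteoglycan of bone, went the other way with 1462 ± 324.4 against 367.2 ± 63.7 FPKM (1.98 ± 0.18). The osteoblast list, with 4 of 21 higher and 6 lower, or 6 and 7 adjusted over the list alone, did not pass (adjusted p = 0.157), but passed without lbSSC replicate 4 (adjusted p = 0.0410). Of 21 chondrocyte genes 5 were higher and 1 lower, also adjusted over the list alone, and the list did not pass (adjusted p = 0.551). It passed in fits chosen after the data were seen, without both vSSC replicates 1 and 3 (adjusted p = 0.0405) and with the ribosomal protein share as a covariate (1.50e-06). Matn3 was at 1506 ± 88.6 against 541.5 ± 85.9 FPKM (1.49 ± 0.13) and the cartilage link protein Hapln1 at 1887 ± 176.3 against 1004 ± 107.6 (0.91 ± 0.12), whereas Matn1 fell.

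Among hypertrophic chondrocyte genes, 4 of 11 were higher and 1 lower, or 5 and 3 adjusted over the list alone, and the list did not pass (adjusted p = 0.304; 0.0330 with fry). Ihh, the signal of prehypertrophic chondrocytes, was at 94.0 ± 8.92 against 32.9 ± 8.01 FPKM (1.51 ± 0.16), and Pth1r, the receptor of parathyroid hormone related protein, at 407.4 ± 12.9 against 191.5 ± 39.5 (1.11 ± 0.14). Col10a1, the collagen of hypertrophic cartilage, fell from 325.5 ± 53.4 in lbSSC to 137.0 ± 24.8 FPKM in vSSC (-1.25 ± 0.15). Skeletal stem cell markers fell as a list, with 8 of 20 lower and 3 higher, also adjusted over the list alone (median -0.34, adjusted p = 0.00129; adjusted p = 0.0554 with an estimated correlation). Grem1, a secreted BMP antagonist, was at 3.32 ± 0.762 against 16.0 ± 2.77 FPKM (-1.98 ± 0.17), and the chemokine Cxcl12 at 12.7 ± 3.85 against 35.7 ± 9.14 (-1.42 ± 0.22). Members of this list that were higher in vSSC included Fgfr3 (0.46 ± 0.10, adjusted p = 0.00882) and Foxa2 (0.74 ± 0.23, adjusted p = 0.0362). The call of Foxa2 was lost in 16 of 30 alternatives and that of Fgfr3 in 2 of 30.

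Lists of marrow stroma, tendon and synovial genes fell in vSSC. In the marrow stroma and adipogenic list 6 of 12 fell and 2 rose, or 7 and 2 adjusted over the list alone (median -0.57, adjusted p = 0.0333; adjusted p = 0.283 with an estimated correlation), and this call was also lost under each of the 3 other scalings (0.0658 to 0.0965) and without vSSC replicate 3 (0.0658). Vcam1, an adhesion molecule, was at 0.876 ± 0.720 against 5.08 ± 0.667 FPKM. In the tendon and ligament list 6 of 12 fell, also adjusted over the list alone (median -0.47, adjusted p = 0.000274; adjusted p = 0.0557 with an estimated correlation), among them Col14a1 (-1.46 ± 0.19) and the proteoglycan Kera (-1.67 ± 0.25). In the synovial and articular list 5 of 11 fell and 1 rose, also adjusted over the list alone (median -0.52, adjusted p = 0.0136; adjusted p = 0.173 with an estimated correlation), with Gdf5, a joint-forming growth factor, at 9.10 ± 2.20 against 21.1 ± 4.06 FPKM. All 4 tested notochord and nucleus pulposus genes were called, 3 higher and 1 lower, also adjusted over the list alone, and the list did not pass (adjusted p = 0.364). The calls of Hopx and Foxa2 among the 3 were each lost in 16 of 30 alternatives, among them median-of-ratios scaling (adjusted p = 0.0544 and 0.0725) and rescaling to one sum (0.0805 and 0.0948). Cd24a was higher, at 508.7 ± 69.4 against 245.6 ± 64.7 FPKM, and Car3, a carbonic anhydrase, lower (-2.06 ± 0.30).

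TGF-beta and IGF, retinoic acid, FGF and Wnt lists fell in vSSC. Of 20 TGF-beta and IGF genes 10 fell and 2 rose, or 13 and 2 adjusted over the list alone (median -0.57, adjusted p = 3.55e-05; adjusted p = 0.131 with an estimated correlation). Igfbp5, an IGF-binding protein, was at 8.85 ± 2.45 against 59.8 ± 17.2 FPKM (-2.62 ± 0.23). Of 10 retinoic acid genes 5 fell, or 6 adjusted over the list alone (median -0.67, adjusted p = 0.000144; adjusted p = 0.131 with an estimated correlation). Of 15 FGF genes 6 fell and 1 rose, also adjusted over the list alone (median -0.33, adjusted p = 0.00153; adjusted p = 0.0554 with an estimated correlation), with Etv5, a transcription factor induced by FGF, at -1.74 ± 0.17. Of 29 Wnt genes 12 fell and 5 rose, also adjusted over the list alone (median -0.36, adjusted p = 0.00716; adjusted p = 0.131 with an estimated correlation). The Wnt members moved apart: the antagonists Sfrp1 and Sfrp2 (-2.14 ± 0.27) fell, while Rspo3, an enhancer of Wnt signalling (1.58 ± 0.16), and Notum, an enzyme that inactivates Wnt proteins (1.10 ± 0.12), rose.

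BMP, Hedgehog and secreted factor lists held changes in both directions and did not pass. In the BMP list 7 of 26 were higher and 7 lower, or 7 and 8 adjusted over the list alone (adjusted p = 0.249; 0.0112 among genes with an FPKM of at least 5), and its mean of 0.01 lay above 0 while its median of -0.06 and the test lay below. Bmpr1b, a BMP receptor, was at 4.24 ± 0.281 against 0.604 ± 0.258 FPKM (1.72 ± 0.16) and Bmp4 at 1.57 ± 0.336 against 7.38 ± 1.32 (-1.70 ± 0.16). In the Hedgehog list 3 of 12 were higher and 4 lower, also adjusted over the list alone (adjusted p = 0.157): the coreceptors Boc (-1.51 ± 0.13) and Gas1 (-1.41 ± 0.13) fell and Hhip (1.02 ± 0.11) rose with Ihh. In the list of secreted and cytokine genes linked to bone metastasis 3 of 15 were higher and 4 lower, or 4 and 7 adjusted over the list alone (adjusted p = 0.184; 0.0350 among genes with an FPKM of at least 5). Mfge8, a secreted glycoprotein that binds phosphatidylserine and a gene the study is known for, was at 1573 ± 49.9 against 1161 ± 107.3 FPKM (0.44 ± 0.11, adjusted p = 0.0159). That call was lost after quantile normalization (0.21, adjusted p = 0.177) and after rescaling to one sum (0.29, adjusted p = 0.0613), and without lbSSC replicate 3 (0.38, adjusted p = 0.0569). Over all alternatives for the gene Mfge8 the adjusted p ran from 0.00904 to 0.177.

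Proliferation and energy metabolism genes were higher in vSSC, together with ribosomal protein genes. Of 18 proliferation genes 15 rose, or 16 adjusted over the list alone (median 0.82, adjusted p = 3.90e-07; adjusted p = 0.160 with an estimated correlation), such as Birc5, a mitotic survival factor, at 38.2 ± 8.54 against 14.8 ± 3.76 FPKM (1.31 ± 0.20). Of 24 glycolysis and hypoxia genes 16 rose and 1 fell, also adjusted over the list alone (median 0.53, adjusted p = 2.29e-05; adjusted p = 0.160 with an estimated correlation). The lactate transporter Slc16a3 was at 214.8 ± 34.7 against 80.7 ± 10.2 FPKM (1.40 ± 0.14) and lactate dehydrogenase Ldha at 1185 ± 151.1 against 571.0 ± 82.6 (1.06 ± 0.14). Of 36 ribosomal protein genes 16 rose, or 28 adjusted over the list alone (median 0.39, adjusted p = 3.28e-06; adjusted p = 0.402 with an estimated correlation). Of 29 oxidative phosphorylation genes 10 rose, or 17 adjusted over the list alone (median 0.37, adjusted p = 0.000118; adjusted p = 0.415 with an estimated correlation), and this call was also lost with fry (0.0618).

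Ribosomal protein genes took 20.1 ± 1.48% of the summed FPKM in vSSC and 16.9 ± 1.43% in lbSSC (exact permutation test over 70 assignments, two-sided, p = 0.0571). The share varied within the groups, with 21.2% and 21.4% in vSSC replicates 1 and 3 and 15.7% in lbSSC replicates 3 and 4. With this share as a covariate, chosen after the data were seen, the ribosomal list had an adjusted p of 0.911 and the oxidative phosphorylation list turned to the other direction with 0.361. The share is computed from ribosomal protein genes themselves, so the loss of their list follows from the fit and tests nothing. It also moves with site, so the fit removes part of the site difference from the other lists. In that fit the lists of stem cell (adjusted p = 0.0620), tendon (0.230), synovial (0.369), osteoclast (0.0620), FGF (0.0552), TGF-beta and IGF (0.0569), retinoic acid (0.112), Wnt (0.0819) and marrow stroma genes (0.0886) no longer passed either. Immediate early and stress genes did not pass as a list (adjusted p = 0.132), passed as lower after quantile normalization (0.0179) and without vSSC replicate 4 (0.00517), and passed as higher with the ribosomal protein share as a covariate (0.0343). The list had 2 of 17 higher and 2 lower, also adjusted over the list alone, among them Dusp1, a phosphatase of MAP kinases, at 740.0 ± 43.2 against 260.3 ± 42.9 FPKM (1.52 ± 0.13). Of 6 interferon response genes 1 was lower, also adjusted over the list alone, and the list did not pass (adjusted p = 0.0798). The list passed without vSSC replicate 1 (adjusted p = 0.0494) and with no filter on low values (0.00804). The called gene was Rsad2, an antiviral enzyme, at -0.75 ± 0.18.

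**Figure D3:**
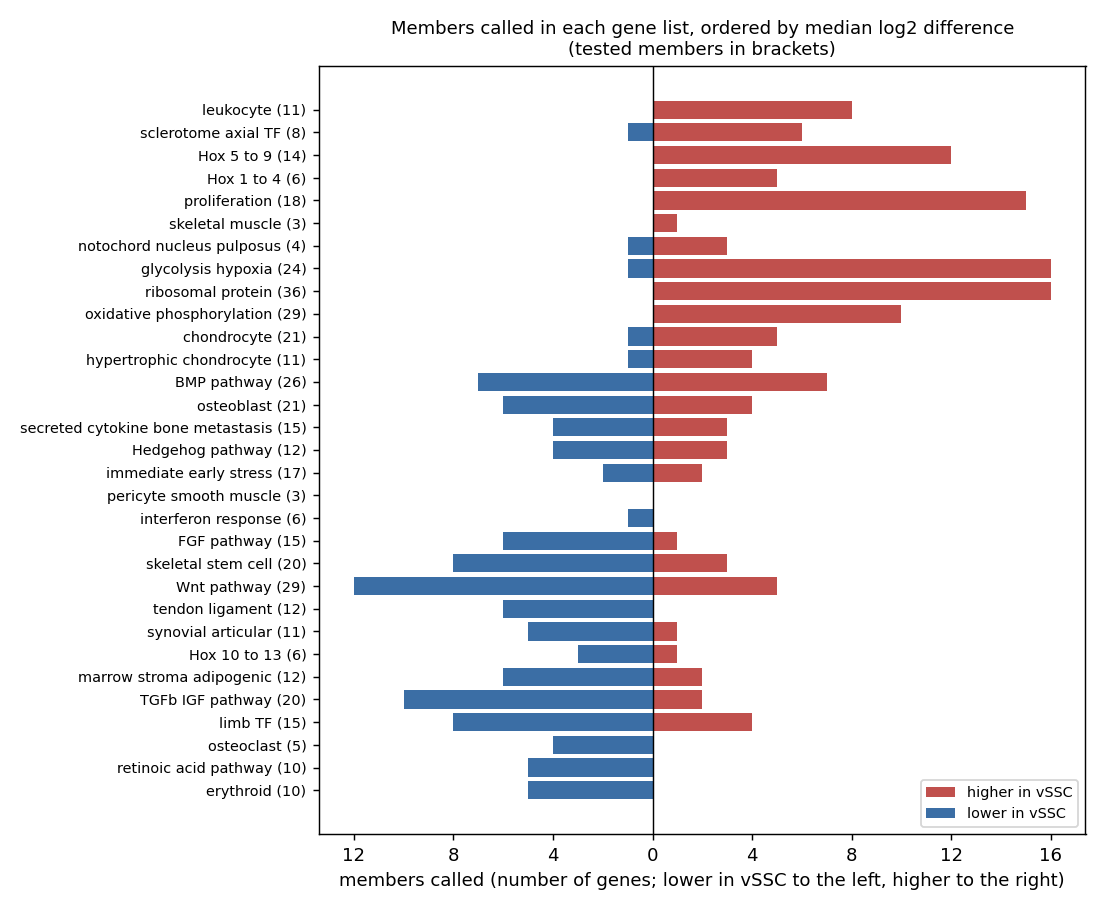
Number of called genes on the x axis, lower in vSSC to the left and higher to the right, for gene lists with at least 3 tested members on the y axis. Bars are counts with no error, tested members stand in brackets, and lists run from the highest median difference (leukocyte, 1.41) to the lowest (erythroid, -0.77).

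Transcripts that mark other cell types differed between the sites. Of 11 leukocyte genes 8 were higher in vSSC, also adjusted over the list alone (median 1.41, adjusted p = 0.000240; adjusted p = 0.205 with an estimated correlation). Besides S100a8, the B cell receptor components Cd79a (5.19 ± 1.18 against 0.999 ± 0.826 FPKM, 1.69 ± 0.26) and Cd79b (1.60 ± 0.28) were among them, with adjusted p of 0.118 and 0.187 with the ribosomal protein share as a covariate. Of 10 erythroid genes 5 were lower in vSSC, also adjusted over the list alone (median -0.77, adjusted p = 4.80e-05; adjusted p = 0.274 with an estimated correlation), with haemoglobin genes at 0.806 ± 0.111% of summed FPKM in vSSC and 1.25 ± 0.402% in lbSSC. In males the share was 0.922% and 0.879% in vSSC and 1.64% and 1.55% in lbSSC, and in females 0.70% and 0.722% in vSSC and 0.864% and 0.942% in lbSSC. Among the called genes was Slc4a1, the anion exchanger of red cells, at 21.2 ± 2.94 against 57.3 ± 18.3 FPKM. Of 5 osteoclast genes 4 fell, also adjusted over the list alone (median -0.67, adjusted p = 0.00116; adjusted p = 0.0554 with an estimated correlation), including the protease Ctsk (-0.92 ± 0.12). Ctsk is also a member of the skeletal stem cell list, so its fall counts in both lists and does not by itself point to osteoclasts. The calls of Mmp9 and Acp5 were lost in 15 of 29 and 8 of 30 alternatives, Mmp9 after quantile normalization (adjusted p = 0.0812) and Acp5 without lbSSC replicate 4 (0.0733), for example.

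Of 3 skeletal muscle genes 1 rose, or 3 adjusted over the list alone (median 0.76, adjusted p = 0.0166; adjusted p = 0.160 with an estimated correlation; 0.343 with no filter on low values), namely Tnnt3, a troponin of fast fibres, at 17.9 ± 3.08 against 3.13 ± 0.408 FPKM. None of 3 pericyte and smooth muscle genes passed, also adjusted over the list alone (list adjusted p = 0.296; 0.0236 with no filter on low values). A single endothelial gene was expressed highly enough to test, Egfl7, at 5.72 ± 1.45 against 2.17 ± 0.501 FPKM (1.07 ± 0.19, adjusted p = 0.00281), so the list had no test. Mitochondrially encoded genes were not analysed here.

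Genes of the sorting markers were low except the positive one. Cd200 was at 109.3 ± 22.5 FPKM in vSSC and 101.0 ± 28.1 in lbSSC, a difference of 0.13 ± 0.19 that did not pass (adjusted p = 0.649). The other 5 fell below the expression filter and the gate list had no test. Pecam1, which encodes CD31, was at 0.190 ± 0.0572 against 0.0950 ± 0.0680 FPKM, Ptprc, which encodes CD45, at 0.525 ± 0.290 against 0.0402 ± 0.0202, and Thy1 at 0.0529 ± 0.106 against 0.386 ± 0.188. Enpep, which encodes 6C3, was at 0.320 ± 0.157 against 1.22 ± 0.438 and Eng, which encodes CD105, at 0.572 ± 0.240 against 0.926 ± 0.168 FPKM.

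**Figure D4:**
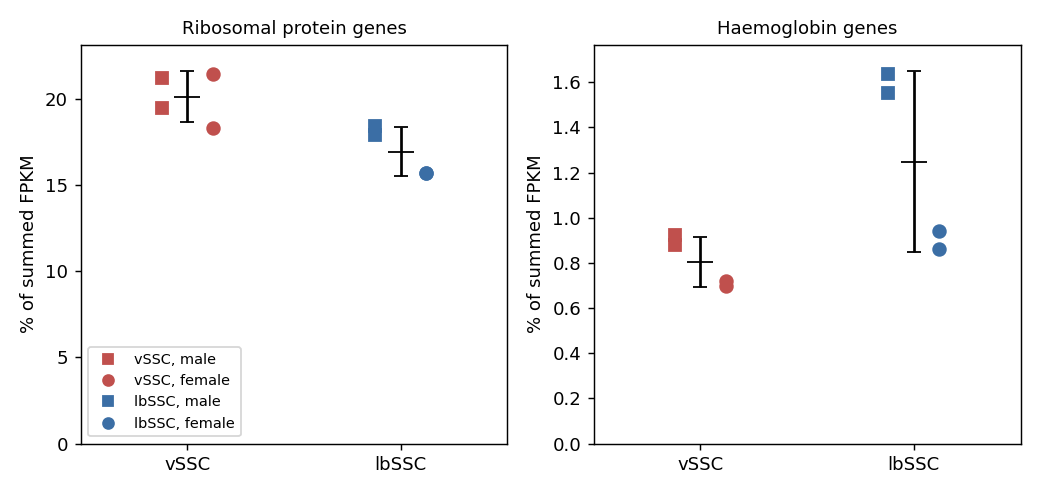
Share of summed FPKM, in percent on the y axis, taken by ribosomal protein genes (left) and haemoglobin genes (right) in the libraries of each site on the x axis. Points are libraries, black lines are means ± SD with n = 4; ribosomal shares run from 15.7% to 21.4%, and haemoglobin shares are highest in the lbSSC males, 1.64% and 1.55%.

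Few genes beyond the Y chromosome were called between males and females. In a model with site as a covariate, 5 of 10729 genes differed, 4 higher and 1 lower in males, while 892 had an unadjusted p under 0.05. All 4 higher genes were Y-linked. Ddx3y was at 34.9 ± 4.90 FPKM in males and 0.0326 ± 0.0295 in females (5.11 ± 0.14, adjusted p = 9.20e-09), and Eif2s3y at 17.5 ± 2.46 against 0.0878 ± 0.116 FPKM (4.08 ± 0.15). Uty, at 6.12 ± 2.31 FPKM, and Kdm5d, at 4.39 ± 0.459 FPKM in males, were listed at 0 in all 4 female libraries. Every library had the Y-linked levels of its labelled sex. Serpina3n, an inhibitor of serine proteases on chromosome 12, was lower in males at 6.47 ± 5.94 against 41.0 ± 19.9 FPKM (-2.81 ± 0.22, adjusted p = 0.000153). The labels used here give no preparation, so for this gene sex cannot be separated from preparation. Without the site covariate the difference of Serpina3n was again -2.81 but no longer passed (adjusted p = 0.993), as the site difference then counts as spread, and its adjusted p ran from 0.000123 to 0.0227 in its other alternatives.

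Genes that escape X inactivation lay lower in males, without passing after adjustment over 10729 genes. In Ddx3x, Eif2s3x and Kdm6a every male library lay below every female library, while the sexes overlapped in Kdm5c. Their unadjusted limma p-values were 0.0191, 0.00285, 0.00426 and 0.110 in that order. Ddx3x differed by -0.29 ± 0.11 (adjusted p = 0.576), Eif2s3x by -0.63 ± 0.16 (adjusted p = 0.456), Kdm6a by -0.51 ± 0.14 (adjusted p = 0.487) and Kdm5c by -0.27 ± 0.15 (adjusted p = 0.652). Whether the site difference itself differed between the sexes was tested with an interaction term in limma over 2 libraries per site and sex. None of 10729 genes passed, with a smallest adjusted p of 0.663, and 405 had an unadjusted p under 0.05. With vSSC replicate 4 left out, 1 gene passed, Gm42742 (3.15, adjusted p = 0.0162), named after its value was seen; vSSC females then had 1 library, which is assumed to vary like the other groups.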

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

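The rule for named genes and the ratio used here were set before the values were seen, and no test in this part was chosen afterwards. Among 280 sets of 4 libraries, each a named gene or library measure in one group, 19 had a library far from the other 3 by Dixon's ratio of gap to range, where chance gives about 1 in 20, or 14.0. No explanation was weighed for these.

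In lbSSC, replicate 1 stood apart in Hoxb7 (ratio 0.919), Slc6a12 (0.839) and Spry4 (0.884). Replicate 3 did so in Zic4 (1.00, the others listed at 0), Col1a1 (0.920) and Dcn (0.908), and replicate 4 in Hoxb6 (1.00, the others listed at 0) and Ctsk (0.904). In vSSC, replicate 1 stood apart in Tbx15 (0.973), Ebf1 (0.862), Mylpf (0.879) and Klf6 (0.975). Replicate 2 did so in Egfl7 (0.895) and Tagln (0.861), replicate 3 in Bpifb1 (0.836), Hoxa13 (0.842) and Mbp (0.918), and replicate 4 in Sfrp1 (0.879) and Bst2 (0.944). The ratios of the low genes in the group where they are near 0 rest on very small differences.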

How the results depend on the processing

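The fits without both vSSC replicates 1 and 3, with the length trend removed, with the ribosomal protein share as a covariate and with the filter reapplied were chosen after the results were seen. Library similarity stayed the largest of its splits in each alternative run. Of 122 named genes called between the sites, 77 kept their call in every alternative that tested them; of 21 lists called, 1 did, Hox groups 5 to 9. With 1 library left out, in both forms of the filter, the site count ran from 1440 to 2991, its higher part from 817 to 1878 and its lower part from 607 to 1113. With the tested genes kept, the lowest counts were 1534 and 839 higher. With the filter reapplied, 1618 were called without vSSC replicate 1, 1577 (835 higher) without vSSC replicate 3 and 1496 (827 higher) without lbSSC replicate 4, and 833 were higher without lbSSC replicate 3. The lists called ran from 18 to 23, the sex genes from 1 to 7 and the interaction genes from 0 to 1. The sex counts of 1 and 2 arose with the filter reapplied, which leaves Y-linked genes untested when a male is left out. Without both vSSC replicates 1 and 3, 1095 genes were called, 503 higher and 592 lower. With the ribosomal protein share as a covariate 623 were called, 237 higher and 386 lower, with 121 higher by at least 1 on the log2 scale, and 12 lists; the share moves with site, so this fit also removes part of the site difference. In that fit Cspg4 turned to 0.76, the immediate early list turned to higher (adjusted p = 0.0343) and the oxidative phosphorylation list to lower (adjusted p = 0.361), and the cause was not tested. Genes lower by at least 1 on the log2 scale numbered 472 and 470 with pseudocounts of 0.1 and 0.01, which widen differences of low genes by construction. They numbered 494 after rescaling to one sum, where 997 genes were higher. As the mean sums were 548787 in vSSC and 495271 in lbSSC, rescaling lowers vSSC relative to lbSSC by construction. How much of the change this accounts for was not tested. At an FPKM of at least 5, with 7069 genes tested, 619 were lower, 182 of them by at least 1, and 3 sex genes were called. With an estimated correlation 1 list was called. With the replicate block 3194 site genes, 22 lists and 0 interaction genes were called, with Hox groups 10 to 13 passing (adjusted p = 0.0447). Deviations of same-numbered libraries correlated by 0.26, -0.09, -0.06 and 0.44, against a mean of -0.05 for the other pairs. As 2 of 4 numbers matched best both ways, whether the numbers pair the samples stays open. Absolute depth is unknown, which leaves the counting error of low genes open.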

Other observations

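The tests of gene families, of transcript length as the whole cause of the ribosomal protein difference, of the ribosomal protein share between libraries, and of erythroid and leukocyte genes by sex were chosen after the results were seen. The other tests were set before their results were seen.

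Grouped by cluster, all tested Hox genes of clusters B and D were called higher in vSSC. Of these, Hoxd4, Hoxd10 and every Hoxb gene but Hoxb2 lay under the filter of 1 FPKM in lbSSC, so they were tested through vSSC alone. Such genes could only lie higher, while Hoxb2, Hoxd8 and Hoxd9 were expressed at both sites. All 7 tested Hoxb genes were called higher (median 2.46, camera adjusted p = 1.67e-10; adjusted p = 0.0114 with an estimated correlation), and all 4 tested Hoxd genes (median 1.48, adjusted p = 4.68e-05; adjusted p = 0.0173 with an estimated correlation). Cluster A split, with 5 of 8 higher and 3 lower (adjusted p = 0.850), the lower ones being Hoxa10, Hoxa11 and Hoxa13, and 2 were higher after median-of-ratios scaling or rescaling to one sum. In cluster C 2 of 7 were higher (adjusted p = 0.463), and Hoxc10 was nearly equal at 33.8 ± 2.42 against 36.0 ± 3.19 FPKM.

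Collagens fell as a family, with 14 of 30 lower and none higher (median -0.64, and from -0.88 to -0.69 under the other scalings, adjusted p = 9.63e-10; adjusted p = 0.142 with an estimated correlation). The fibrillar Col3a1 (-0.97), Col5a1 (-1.40) and Col5a2 (-1.38) fell with Col1a1, while Col2a1 of cartilage, at 10870 ± 3960 against 14150 ± 4270 FPKM, did not pass (adjusted p = 0.301). Of 6 IGF-binding proteins 5 fell and Igfbp2 rose (adjusted p = 0.000235; adjusted p = 0.0187 with an estimated correlation). Of 12 small leucine-rich proteoglycans 3 rose, Omd, Aspn (1.91) and Epyc (0.89), and 4 fell (adjusted p = 0.476).

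The number of site genes, 2518, was reached by 1 of the 35 splits of the libraries, the real one. That share is the smallest this design allows, so chance is argued against and not excluded. The highest other split gave 4, but the other splits mix the sites, so the site difference counts as spread in them. For sex, 2 of 34 splits, the real one included, gave at least the 5 genes called, so chance cannot be excluded for the number of genes. It is excluded for the Y-linked genes among them by their levels, as Ddx3y was at 28.7 FPKM or more in every male and 0.06 or less in every female. The other was vSSC replicates 1 and 3 with lbSSC replicates 1 and 2, with 607 genes. That split sets the libraries with the higher ribosomal protein share in each site against the others, which points to a structure of the samples. In lbSSC that split is the one between males and females, and in vSSC it is not, so the share cannot be separated from sex within lbSSC.

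Ribosomal protein genes were higher in vSSC relative to all genes, by a mean of 0.36 ± 0.11 (SE). With the length trend removed the difference was 0.17 ± 0.03, above 0 by more than its spread between libraries. That argues against the fitted length trend as the whole cause. The trend was smooth and fitted without ribosomal protein genes, so a length bias that it missed cannot be excluded. The list passed with camera (adjusted p = 0.000309, and 0.209 with an estimated correlation). Whether length accounts for most of it cannot be told apart, since the value left lies within its error of the bound set beforehand, 0.5 times the first value. Variation between libraries unrelated to site stays a candidate explanation, as the share of ribosomal protein genes gave an exact permutation p of 0.0571 over 70 assignments. A biological difference between the sites also stays open and untested.

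Leukocyte transcripts were higher in vSSC although the gate removed CD45-positive cells, and Ptprc, which encodes CD45, was at 0.525 ± 0.290 against 0.0402 ± 0.0202 FPKM, too low to be tested, with every vSSC library above every lbSSC library. A single vSSC library as the source is argued against, since the same 8 genes stayed called whichever vSSC library was left out. More leukocyte RNA in the vSSC libraries cannot be told apart from other causes. A list of neutrophil genes cannot test the B cell genes Cd79a and Cd79b, which are among the called leukocyte genes. Of 22 separate neutrophil genes 9 were tested and 8 lay higher, but their median of 0.35 fell between the bounds set beforehand. Of the 9, 2 were called, both higher, Lcn2 at 13.6 ± 3.96 against 4.71 ± 2.42 FPKM (adjusted p = 0.00561) and Ltf with a log2 difference of 1.15 ± 0.34 (adjusted p = 0.0293), while Anxa3, the next most abundant after Lcn2, was at 5.61 ± 1.98 against 5.03 ± 1.49 (adjusted p = 0.739). A biological difference between the sites stays open and untested, and none of the 22 is in the leukocyte list, whose result had been seen before they were chosen.

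Erythroid transcripts lay higher in male than in female long bone libraries in all 10 tested genes (median 0.89), with haemoglobin at 1.64% and 1.55% of summed FPKM in males and 0.864% and 0.942% in females. In vSSC 9 of 10 lay higher in males (median 0.49). Over the erythroid list, fry gave an adjusted p of 0.00268 for sex and 0.147 for its interaction with site. The leukocyte list was higher in males too (0.00268, interaction 0.346). These p-values were adjusted over the erythroid and leukocyte lists alone. The erythroid list was tested after its difference between males and females had been seen, so its p is not independent evidence. Reads shared between haemoglobin paralogs are argued against as the cause of the whole pattern, though not for the haemoglobins themselves, since 100% of the 6 genes other than haemoglobins lay higher in the long bone males. Erythroid RNA that differs between preparations rather than sexes cannot be told apart from sex, as the labels used here give no preparation. If a replicate number stood for a preparation, 0 numbers would hold both sexes. The gate removed TER119-positive cells, and a difference between the sexes stays open, since these libraries cannot separate it from preparation.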
